A study of Homo sapiens with 6 samples.

How the data were processed

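RNA sequencing was analysed in LX2, a line of activated human hepatic stellate cells (the collagen-producing cells of the liver). The cells were transfected for 48 h with small interfering RNA against AURKA (siAURKA) or with control small interfering RNA (siNC), with 3 libraries in each of the 2 groups. The 6 libraries were grouped by their labels, and the replicate numbers are those of the labels. The labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

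The authors deposited a single table of whole numbers for 58243 Ensembl gene identifiers, read here as estimated counts without scaling. Per the submitters' processing notes, reads were aligned with HISAT2 to GRCh38. The counting tool, its use of strand and the annotation release are not given in the sources used here. In the deposited estimated counts, between 30.3% and 34.0% of the values from 1 to 24 in a library were multiples of 4. Equal frequencies of all these values would give 25%. How these values arose is not known. If 1 fragment is worth about 4 units, the column totals overstate the depth by that factor. Column totals ran from 23366242 to 53357402 units, or 5841560 to 13339350 after division by 4. Since the values are whole, rounding to whole numbers before the count tests altered nothing. On that assumption, which gives the more cautious floor, a level of 3 fragments, or 12 units, corresponds to 0.514 CPM in the shallowest library and 0.225 CPM in the deepest. That floor covers counting error only.

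Identifiers were matched without version to GENCODE release 29 (GRCh38), which gave symbols, coordinates, exonic length, GC content and the share of each gene's exonic bases lying inside exons of other genes. Of the identifiers, 57980 matched and 263 did not; unmatched identifiers held at most 0.0292% of a library's total. All 37 genes of the mitochondrial chromosome were listed at 0 in every library and were not analysed further. As the counting is not stated to use strand, values of overlapping, antisense and read-through genes are uncertain.

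Genes were kept by the default filter of filterByExpr, which left 18775. The main test was edgeR's quasi-likelihood F-test with TMM scaling on siNC against siAURKA, without covariates, at a Benjamini-Hochberg adjusted p (FDR) of 0.05. CPM values are TMM-normalised, apart from the floors, which use library totals, and log2 fold changes are siAURKA over siNC. Gene lists were tested with limma's camera on log2 CPM (prior count 2) at the preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 22 lists that had at least 3 tested members, out of 24 lists. Camera is two-sided and compares a list with all other tested genes. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

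The lists covered Aurora kinase A partners, mitosis, DNA replication, p53 targets, collagens, matrix proteins and crosslinking, matrix turnover, contractile and myofibroblast genes, the TGF-beta pathway, quiescent stellate cell markers, YAP targets, MAPK response, NF-kB and inflammatory mediators, and interferon-stimulated genes. Further lists held the unfolded protein and ATF4 response, cholesterol synthesis, hypoxia and glycolysis, apoptosis regulators, autophagy and lysosome genes, mitochondrially encoded transcripts, and markers of hepatocytes, cholangiocytes, endothelium, and macrophages and leukocytes. The lists, the main test, the other settings to try and the rule for named genes were fixed before the data were examined. That rule named AURKA, then up to 12 genes per direction with a symbol, an adjusted p below 0.05, a mean count of at least 50 and no overlap between the groups, then up to 4 members of each list by smallest p-value. Some list members that the rule names are not reported here. Its second part named 0 genes with the main test. The same part was therefore applied to DESeq2 with a replicate block, a fit chosen after the main test had called no gene.

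Whether replicate numbers pair the libraries was checked from deviations of log2 CPM from the group means. Same-numbered libraries correlated at 0.647, 0.477 and 0.302 for numbers 1, 2 and 3, all above 0.1, while other combinations ranged from -0.525 to 0.040. Deviations cancel out within a group, so the low values of other combinations follow in part from the high same-numbered ones. The numbers were taken to pair the libraries on the same-numbered values. This pairing comes from the data, because the labels name no shared day or batch.

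edgeR and DESeq2, each with and without the replicate block, were tested on simulated counts for 17973 genes with 200 changed. The counts used the library sizes of these 6 libraries, means fitted by replicate number and dispersions fitted with the replicate block. Each gene's replicate effect was thus built in, which favours fits with the block by construction. limma-voom was not simulated. Without the replicate block edgeR recovered 0% of 2-fold and 0% of 4-fold changes, and with the replicate block 36% and 89%, with 16 false calls among 141. DESeq2 recovered 0% and 61%, with 2 false calls among 63. DESeq2 with the replicate block recovered 52% and 95%, but 51 of its 198 calls were false. In simulated lists of genes drawn at random, camera gave an unadjusted p below 0.05 in 3% of 100 unchanged lists. The same threshold was passed by 100% of 20 lists of 30 genes shifted by 0.5 on the log2 scale. These shares need not hold for lists of correlated genes, such as mitosis with an estimated correlation of 0.40.

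Settings fixed beforehand as comparisons were RLE factors, library totals alone, no low-count filter, a filter of 5 CPM in 3 libraries, DESeq2, limma-voom, each library left out in turn, the replicate block, and, for lists, an estimated correlation and fry. Settings chosen after seeing the data were DESeq2 and limma-voom with the replicate block, edgeR on values divided by 4, offsets for each library's trend with GC content and length together with the replicate block, the replicate block without both libraries numbered 2, and camera with the replicate block and an estimated correlation. The GC and length trends were fitted by loess with a span of 0.4 over genes above a log2 CPM of 3.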

Results

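Expression was measured in LX2 cells 48 h after transfection with siAURKA or siNC, in 3 libraries per group. The comparison asks how gene expression in these stellate cells differs when AURKA, which encodes the mitotic kinase Aurora A, is knocked down. Deposited totals were 41764470, 23366242 and 35222906 units in siNC replicates 1, 2 and 3, and 53357402, 33196829 and 42714445 units in siAURKA replicates 1, 2 and 3. Between 21551 genes (siNC replicate 2) and 26672 genes (siAURKA replicate 1) had a value above 0.

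AURKA transcript was 2.43-fold lower after siAURKA. Its level was 119.6 ± 21.7 CPM in siNC and 49.3 ± 2.07 CPM in siAURKA (mean ± SD, n = 3), with siNC libraries at 135.8, 128 and 95.02 CPM and siAURKA libraries at 49.8, 47.0 and 51.1 CPM. The groups did not overlap, and AURKA was lower in 3 of 3 same-numbered pairs, by log2 ratios of -1.45, -1.44 and -0.90. AURKA (ENSG00000087586) lies on the minus strand of chromosome 20 at 56369389 to 56392337 (GRCh38), and none of its exonic bases overlap another gene. The log2 fold change was -1.28 (SE 0.28), with an adjusted p of 0.9999 by edgeR (0.00203 before adjustment). A two-sided exact permutation test on log2 CPM gave p = 0.1, the smallest that 3 against 3 libraries allow. DESeq2 gave an adjusted p of 0.0314 for AURKA, and DESeq2 with the replicate block 1.395e-06.

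**Figure D1:**
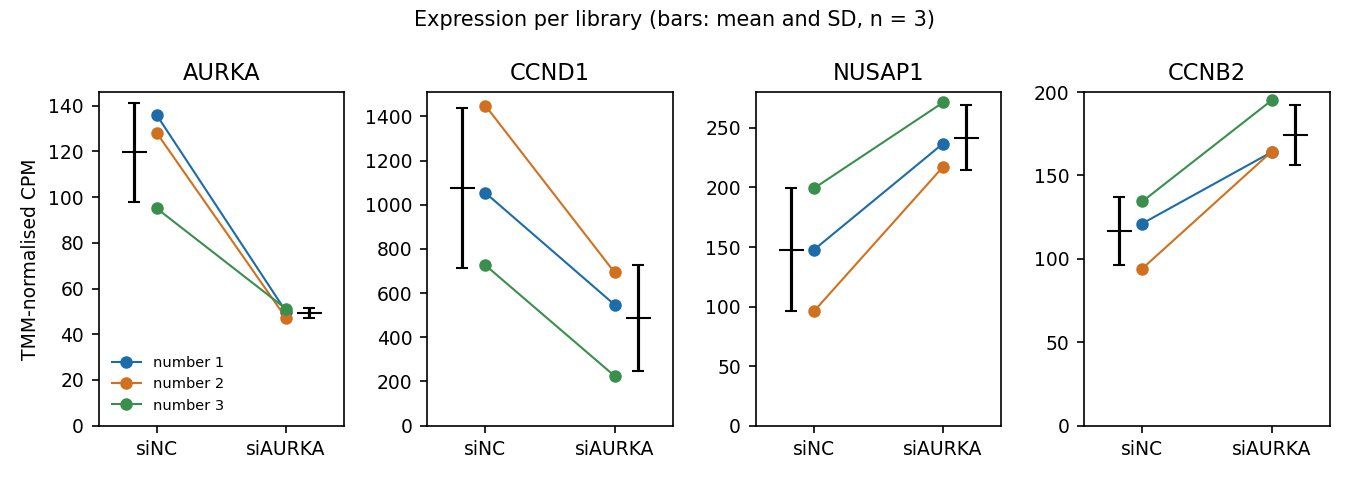
TMM-normalised CPM of AURKA, CCND1, NUSAP1 and CCNB2 in each library, with points of one colour joined for libraries of the same number and black bars giving mean and SD (n = 3). AURKA and CCND1 lay lower, and NUSAP1 and CCNB2 higher, after siAURKA in all 3 pairs.

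Over all 18775 tested genes, edgeR called 0 at an adjusted p of 0.05. Unadjusted p-values below 0.05 numbered 234, where chance alone gives 939. DESeq2 called 17 genes (9 higher, 8 lower) and limma-voom 0. With the replicate block edgeR and limma-voom each called 0, with 1591 and 1759 unadjusted p-values below 0.05, while DESeq2 with the replicate block called 246 genes, 94 higher and 152 lower. Those include 14 of the 17 calls made by DESeq2 without the block. The groups did not overlap for 1098 genes, or 5.85%, against 10% by chance if the 6 libraries were exchangeable; libraries paired by number are not, so that share is no measure of how many genes changed. Same-direction changes in all 3 pairs were found for 35.6% of genes (3369 higher, 3310 lower), against 25% by chance if the pairs were independent. Genes share trends between libraries, so this excess does not measure how many genes changed. Across tested genes the log2 ratios correlated at only 0.063 between pairs 1 and 2, 0.076 between 1 and 3 and 0.126 between 2 and 3.

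The first principal component of log2 CPM held 50.6% of the variance and ran from -90.6 and -81.8 in siNC and siAURKA replicate 1 to 43.5 in siAURKA replicate 2 and 120.5 in siNC replicate 2. Same-numbered libraries correlated at 0.973, 0.943 and 0.966 in log2 CPM, and libraries of one group at 0.881 to 0.955. The siAURKA library numbered 2 correlated more with both libraries numbered 3, at 0.955 each, than with siNC replicate 2. siNC replicate 2 stood apart, with the smallest total, a count-weighted mean GC content of 53.3% against 49.2% to 52.2% in the other 5 libraries, and MALAT1, a nuclear long noncoding RNA, at 72.5 CPM against 145.3 to 410.5. Both libraries numbered 1 differed too, with mean GC contents of 49.2% in siNC and 49.4% in siAURKA. Their count-weighted mean log2 exonic lengths were 12.47 and 12.43, against 12.08 to 12.15 in the others. Of 90 list members that the naming rule selects, 48 lost over 50% of their edgeR log2 fold change or changed sign when 1 library was left out, 25 of them with the greatest loss without siNC replicate 2. The value of 65 of the 90 moved by over 1.5 times. edgeR had called none of the 90.

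**Figure D2:**
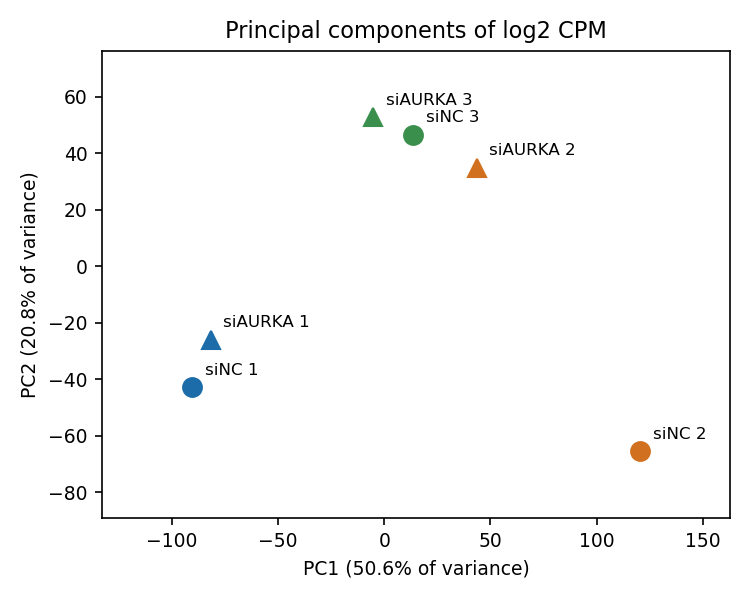
First and second principal components of log2 CPM for the 6 libraries, with circles for siNC, triangles for siAURKA and one colour per replicate number. The siNC library numbered 2 sits farthest out on the first component, at 120.5, and both libraries numbered 1 sit at the other end.

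Genes of mitosis were called as a list by camera, higher after siAURKA. Of 33 members, 30 had a log2 fold change above 0, with a median of 0.36, and 26 were higher in all 3 pairs against 0 lower. NUSAP1, a spindle-associated protein, was at 147.6 ± 51.6 CPM in siNC and 241.9 ± 27.4 CPM in siAURKA (n = 3). Cyclin B2 (CCNB2) was at 116.6 ± 20.5 and 174.4 ± 17.8 CPM, cyclin B1 (CCNB1) at 310.3 ± 87.9 and 431.5 ± 73.1 CPM, and PRC1, a spindle midzone protein, at 258.4 ± 71.9 and 345.4 ± 41.8 CPM. Camera gave an adjusted p of 3.139e-05 for the list, and 4.832e-07 with the replicate block. With an estimated correlation the adjusted p was 0.62, and without siNC replicate 2 it was 0.26. That library had the highest GC content and the smallest total. A two-sided exact permutation test on the list's mean log2 CPM gave p = 0.4, where 0.1 is the smallest possible. That test regroups all 6 libraries freely and ignores the pairing, so its p does not speak against a change within pairs. In 6 of the 9 other splits of the libraries into 3 and 3 the mitosis list also had an adjusted p below 0.05 by camera, the lowest 0.00019, so a small p from camera alone does not set the treatment apart from other groupings. In the other splits that also separate all 3 pairs, the adjusted p by camera was 0.049, 0.98 and 0.0094. edgeR called 0 members, both over all genes and adjusted over the list alone. NUSAP1 and PRC1 share 62.2% and 58.4% of their exonic bases with other genes. DESeq2 with the replicate block called 4 as higher, which are NUSAP1 and CCNB2 and, named after their values were seen, BUB1B and MKI67. MKI67, the proliferation marker Ki-67, was higher in 2 of 3 pairs. Without 1 library the edgeR log2 fold change ran from 0.0048 to 3.04 for MKI67 and from 0.16 to 1.16 for BUB1B.

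Other cell cycle lists were not called. The DNA replication list (33 members) had a median log2 fold change of 0.08 and an adjusted p of 0.53 by camera. MCM2, a subunit of the replicative helicase, had a log2 fold change of -0.49 and was lower in 3 of 3 pairs, whereas POLE2 had 0.75, RFC4 0.31 and RRM1 0.33. Among 11 Aurora kinase A partners, 10 had values above 0, with a list median of 0.20. BORA, a cofactor in Aurora A activation of PLK1, had 0.81, TPX2, which activates Aurora A on the spindle, had 0.42, AURKC had 0.64 and NEDD9 had -0.44. The partner list's adjusted p was 0.083 by camera, and 0.039 with the replicate block (0.60 with an estimated correlation besides). The 26 p53 targets had a median of -0.16 and an adjusted p of 0.15. TP53INP1 at -1.41 and CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, at -1.09 were lower in 3 of 3 pairs, as were PLK3 at -0.62 and PPM1D at -0.40. TP53INP1 was at -0.27 without siNC replicate 1, and CDKN1A at -0.095 and PLK3 at -0.15 without siNC replicate 2. Of the p53 targets, DESeq2 with the replicate block called TP53INP1 alone.

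Genes of hypoxia and glycolysis were called as a list by camera, lower after siAURKA. Of 18 members, 16 had a log2 fold change below 0, with a median of -0.31, and 7 were lower in all 3 pairs against 1 higher. Adrenomedullin (ADM) was at 30.01 ± 9.64 CPM in siNC and 14.4 ± 4.53 CPM in siAURKA (n = 3). The glucose transporter SLC2A1 was at 152.3 ± 51.7 and 98.2 ± 19.5 CPM, lactate dehydrogenase A (LDHA) at 1214 ± 676 and 738 ± 39.4 CPM, and VEGFA at 47.4 ± 34.4 and 26.1 ± 3.19 CPM. Camera gave an adjusted p of 0.0041, or 0.58 with an estimated correlation. It was 0.26 without siNC replicate 2 and 0.064 without siAURKA replicate 1. A two-sided exact permutation test on the list's mean log2 CPM, which again ignores the pairing, gave p = 0.2. VEGFA was at a log2 fold change of -0.089 without siNC replicate 2 (-0.86 with it), and LDHA at -0.16 without siNC replicate 3 (-0.72 with it). edgeR called 0 members over all genes and 0 adjusted over the list alone. With the replicate block it called ADM adjusted over the list alone, and DESeq2 with the replicate block called ADM too.

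Lists of fibrosis genes, the products of activated stellate cells, were not called. Among 16 collagens the median log2 fold change was 0.10 (adjusted p = 0.64 by camera). COL1A2, a chain of type I collagen, had 1.06 at 4.35 ± 1.29 CPM in siNC and 9.11 ± 2.56 CPM in siAURKA, COL4A1 had 0.27, COL6A1 -0.22 and COL16A1 0.21. The 28 genes of matrix proteins and crosslinking had a median of -0.12 (0.17), with the lysyl oxidase LOXL2 at -0.49, PLOD2 at -0.60, SPARC at -0.68 and LAMA4 at 0.55. The 18 genes of matrix turnover had a median of -0.20 (0.60). Among them PLAT, which encodes tissue plasminogen activator, was at 499.7 ± 123.8 CPM in siNC and 304.1 ± 38.7 CPM in siAURKA and lower in 3 of 3 pairs, CTSK had a log2 fold change of 0.70, PLAUR -0.50 (0.0014 without siNC replicate 2) and MMP19 0.32. PLAT was called with the replicate block, by edgeR adjusted over the list alone and by DESeq2 over all genes. The 18 contractile and myofibroblast genes had a median of -0.06 while camera's direction was up (0.60), with smooth muscle actin (ACTA2) at 0.52, ACTG2 at 0.58, TPM1 at -0.35 and PDGFRB at -0.35. The 22 TGF-beta pathway genes had a median of -0.14 (0.19), with TGFBI at -0.43, SMAD6 at -0.61, PMEPA1 at -0.83 and LTBP2 at 0.65. Of 9 quiescent stellate cell markers the median was -0.17 and the mean 0.07, with camera's direction down (0.75), with GFAP at -0.91, HAND2 at -0.39, SPARCL1 at 1.59 and PPARG at 1.01. PPARG (0.192 and 0.411 CPM) and SPARCL1 (0.530 and 1.59 CPM, at 0 in siAURKA replicate 3) were near the floor, and SPARCL1 was at 0.52 without siAURKA replicate 2. GFAP was at -0.050 and HAND2 at -0.089 without siNC replicate 3. Without siNC replicate 1 PLOD2 was at -0.049 and PDGFRB at -0.039.

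Growth and inflammatory signalling lists had fitted medians below 0 without being called by camera in the main test. Cyclin D1 (CCND1), which drives entry into the cycle downstream of MAPK signalling, was at 1077 ± 361.9 CPM in siNC and 488.6 ± 239.8 CPM in siAURKA (n = 3) and lower in 3 of 3 pairs. Its adjusted p was 0.9999 by edgeR (0.0451 before adjustment). With the replicate block CCND1 was called by edgeR adjusted over the list alone, and by DESeq2 over all genes at an adjusted p of 7.465e-06. The 18 MAPK response genes had list medians of 0.16, -0.46 and -0.23 in pairs 1, 2 and 3. Their fitted median was -0.32 and the adjusted p 0.083 by camera (0.039 with the replicate block), with DUSP5 at -0.69, ETV5 at -0.47 and EPHA2 at -0.39. The 19 YAP targets had a median of -0.23 with the same pair of adjusted p-values, and NUAK2 had -0.82, CCN2 -0.61, GADD45B -0.56 and ARHGEF17 -0.43. DESeq2 with the replicate block called NUAK2. The 23 NF-kB and inflammatory mediators had a median of -0.56 and an adjusted p of 0.083 (0.024 with the replicate block), with the cytokine CSF2 at -2.05, the chemokine CXCL8 at -1.22, ICAM1 at -0.81 and TNFAIP3 at -0.71. Their list medians in pairs 1, 2 and 3 were 0.03, -1.13 and 0.06, and without siNC replicate 2 CXCL8 was at 0.59, CSF2 at 0.36, TNFAIP3 at 0.12 and ICAM1 at -0.046. In the MAPK and YAP lists ETV5 was then at 0.0011, DUSP5 at -0.0018, EPHA2 at -0.15 and CCN2 at -0.13. Calls gained with the replicate block are lost when the correlation is also estimated, where every list tested had an adjusted p of 0.597 or more.

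Apoptosis regulators were mixed, with more members lower than higher. BMF was at 18.2 ± 2.28 CPM in siNC and 9.83 ± 0.761 CPM in siAURKA (n = 3), and BCL2L11, which encodes BIM, at 36.3 ± 29.3 and 9.37 ± 7.499 CPM, each lower in 3 of 3 pairs. In pair 2 the log2 ratio of BCL2L11 was only -0.12. The 24 members had a median log2 fold change of -0.26 and an adjusted p of 0.083 by camera (0.028 with the replicate block). Of them 17 had a log2 fold change below 0 and 7 above, with 10 lower and 3 higher in all 3 pairs. edgeR called 0 members, and DESeq2 with the replicate block called BMF, BCL2L11 and, named after its value was seen, APAF1. Without 1 library the edgeR log2 fold change ran from -2.48 to -0.39 for APAF1 and from -2.86 to -1.28 for BCL2L11.

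Metabolic and stress lists were not called. The 21 cholesterol synthesis genes had a median of 0.19 (adjusted p = 0.090 by camera), with HMGCS1 at 1.07, SQLE at 0.53 and CYP51A1, whose exonic bases overlap other genes by 83.2%, at 0.36. The 23 genes of the unfolded protein and ATF4 response had a median of -0.08 (0.15), with ASNS at -1.16, PSAT1 at -0.75, SHMT2 at -0.72 and HYOU1 at -0.45; without siNC replicate 2, ASNS was at 0.37, PSAT1 at 0.08 and SHMT2 at -0.13. The 26 interferon-stimulated genes had a median of 0.06 with camera's direction up but a mean difference in log2 CPM of -0.01 (0.76), with IFI44L at 0.92, IRF9 at 0.82, HERC5 at 0.41 and STAT2 at -0.43. The 20 autophagy and lysosome genes had a median of -0.005 (0.60), with GABARAPL1 at -1.19, SQSTM1 at -0.77 (0.31 without siNC replicate 2), NEU1 at -0.50 and CTSL at 0.28. The 13 mitochondrially encoded transcripts were listed at 0 in every library.

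**Figure D3:**
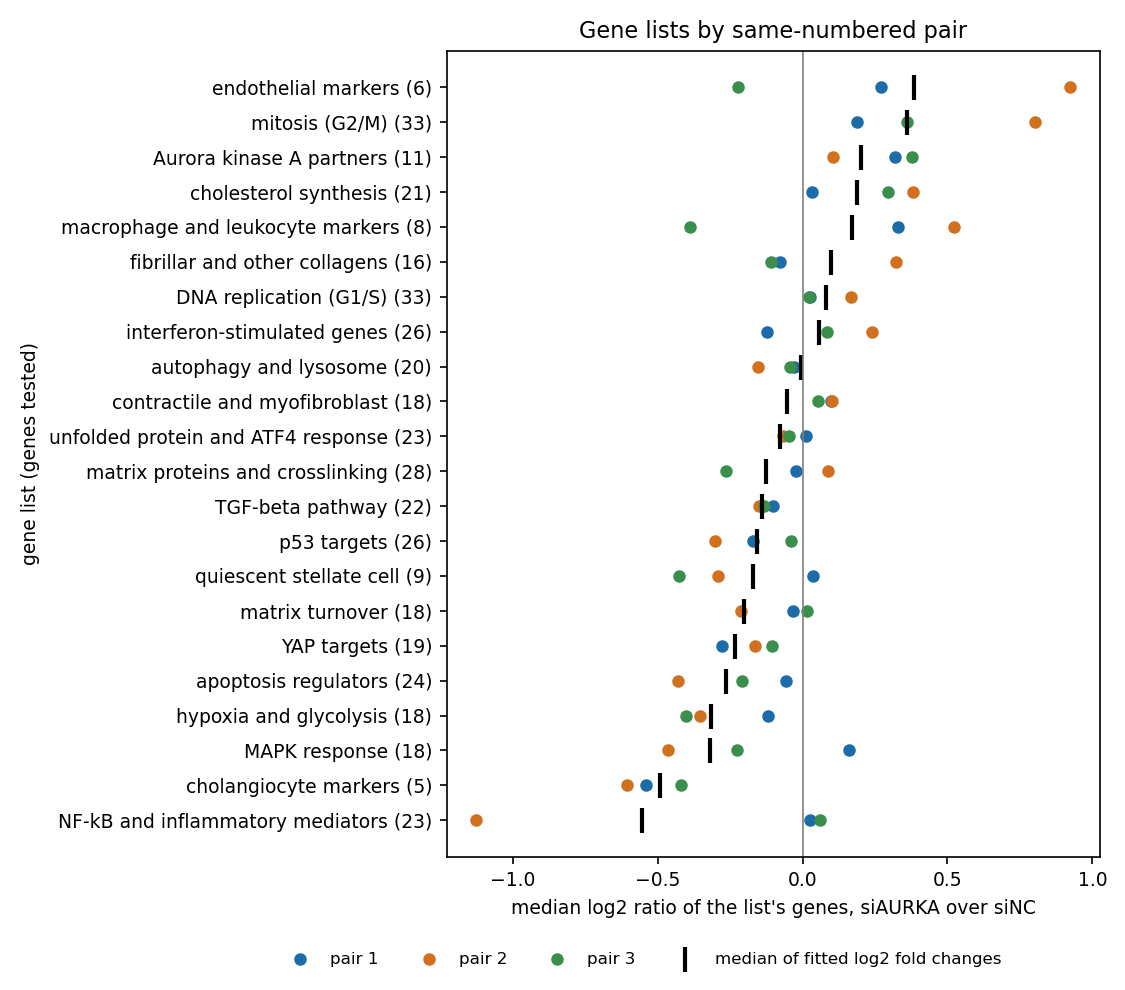
Median log2 ratio of siAURKA over siNC for the genes of each tested list, with one coloured point per same-numbered pair and a black bar for the median of the fitted log2 fold changes (number of genes in parentheses). The mitosis points lie above 0 in all 3 pairs, at 0.19, 0.80 and 0.36, and the NF-kB list is far below 0 in pair 2, at -1.13.

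Markers of other liver cell types were mostly low. Albumin (ALB), APOB and TTR were among 8 of 16 hepatocyte markers at 0 in all 6 libraries, where the floor of the deepest library is 0.225 CPM. All genes of the mitochondrial chromosome were also listed at 0, so a 0 here need not mean low expression. Of the hepatocyte markers 2 were tested, SERPINA1 (27.35 CPM on average, log2 fold change -0.29) and CYP2E1 (0.870 CPM, -0.15). The 5 cholangiocyte markers tested had a median of -0.49 (adjusted p = 0.17 by camera), with KRT7 at -0.74, SPP1 at -1.02, KRT19 at -0.49 and SOX9 at -0.27. The 6 endothelial markers had a median of 0.39 (0.67) and a mean difference in log2 CPM of -0.03, with PECAM1 at 0.85, VWF at 0.999, TEK at 0.63 and STAB1 at -0.99. The 8 macrophage and leukocyte markers had a median of 0.17 (0.75), with CD14 at -0.55 and LYZ at -0.54. C1QA at 0.149 and 0.659 CPM and C1QB at 0.165 and 0.435 CPM in siNC and siAURKA stood close to the floor. So did SPP1 at 1.04 and 0.51 CPM, with 0 in siNC replicate 2, and its log2 fold change was -0.050 without siNC replicate 3. Without siNC replicate 2, SERPINA1 was at 0.13, KRT19 at 0.36 and SOX9 at 0.15; CYP2E1 was at 0.023 without siNC replicate 1, TEK at -0.098 without siAURKA replicate 1 and VWF at -0.15 without siAURKA replicate 2. TIE1 at 119.2 CPM, CD68 at 61.2 CPM and SOX9 at 53.7 CPM were the most abundant of these markers.

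Single genes with large differences were named from DESeq2 with the replicate block, a fit chosen after the main test gave 0 calls, in which 122 genes met the naming conditions (53 higher, 69 lower). RBMS2, which encodes an RNA-binding protein, was at 17.97 ± 5.89 CPM in siNC and 76.7 ± 7.86 CPM in siAURKA (n = 3), a log2 fold change of 2.12 (SE 0.23, adjusted p 3.898e-16 by DESeq2 with the replicate block). The cyclin-dependent kinase CDK14 was at 14.2 ± 6.62 and 45.1 ± 19.5 CPM, LIMS1 (PINCH1, a focal adhesion protein) at 22.1 ± 21.4 and 50.5 ± 3.59 CPM, and the anti-apoptotic BCL2L2 at 11.6 ± 9.52 and 33.6 ± 0.480 CPM. Also higher were the zinc finger gene ZNF227 (1.67 in log2 fold change), the anion transporter SLC26A1 (1.48), the dynein heavy chain DNAH11 (0.968 to 21.1 CPM) and SCHIP1 (1.17 to 9.86 CPM). On the lower side, MAPK14, which encodes the stress kinase p38 alpha, was at 49.6 ± 13.8 and 16.7 ± 11.03 CPM, the RNA polymerase III subunit POLR3G at 81.3 ± 21.1 and 25.1 ± 11.4 CPM, and the chloride transporter CLCN5 at 18 ± 17.03 and 3.06 ± 1.91 CPM. SCAMP5 (-1.54), FAM219B (-1.62), ZNF562 (-1.87) and the noncoding CTBP1-DT (-1.72) and PCBP1-AS1 (-1.53) were lower as well. edgeR called 0 of the 24 genes named from it here and in the next paragraph, with or without the replicate block. Without 1 library 8 of the 24 moved by over 1.5 times in edgeR log2 fold change, among them LIMS1 (0.80 to 2.38, against 1.19 with all 6 libraries), BCL2L2 (1.21 to 2.46, against 1.54), CLCN5 (-3.10 to -1.43, against -2.56), FAM219B (-2.23 to -0.83, against -1.22) and SCAMP5 (-2.12 to -0.90, against -1.78). In pair 1 the log2 ratio was only -0.27 for MAPK14, -0.14 for FAM219B, -0.41 for SCAMP5 and 0.03 for LIMS1. MAPK14 was at -2.62 and -2.31 in pairs 2 and 3.

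Several of the named genes share exons with others, so that their values are uncertain. ZC3H11A rose from 12.8 ± 20.1 to 122.2 ± 61.2 CPM by this fit, while ZBED6, which has 96.0% of its exonic bases within the exons of ZC3H11A on chromosome 1, fell from 131.5 ± 66.3 to 26.8 ± 16.01 CPM. SCHIP1 was higher while IQCJ-SCHIP1, a read-through transcript of the same locus named after its value was seen, was lower (log2 fold change -1.29). Likewise BCL2L2 was higher while the read-through BCL2L2-PABPN1, also named after its value was seen, had a log2 fold change of -1.10 (adjusted p = 0.22 by DESeq2 with the replicate block). The read-through genes TMEM256-PLSCR3 (0.322 to 6.71 CPM) and ABHD14A-ACY1 (1.68 to 6.75 CPM) and the antisense MYL12-AS1 (0.819 to 16.9 CPM) were higher. AMIGO3 (27.0 to 3.06 CPM), KIAA0408 (7.08 to 1.49 CPM) and the read-through CFAP298-TCP10L (3.29 to 0.0223 CPM, the latter under the floor) were lower, with 99.7%, 82.6% and 100% of their exonic bases inside other genes' exons. Without 1 library the edgeR log2 fold change ran from 2.71 to 6.66 for ZC3H11A, 1.43 to 4.66 for ABHD14A-ACY1 and -10.19 to -2.58 for AMIGO3. In the simulation of this fit 51 of 198 calls were false.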

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

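Alternatives with DESeq2 or limma-voom and the replicate block, with values divided by 4, with GC and length offsets, without both libraries numbered 2, and with the replicate block plus an estimated correlation were tests chosen after the results were seen. The AURKA log2 fold change stayed below 0 in every alternative and passed the threshold under DESeq2 (-1.29) and DESeq2 with the replicate block (-1.28) only; leaving out each library gave -1.41 to -1.17. Against 0 genes called by edgeR, DESeq2 called 17 (9 higher, 8 lower, 17 at 2-fold or more) and DESeq2 with the replicate block 246 (94 higher, 152 lower, 117 at 2-fold or more). Leaving out each library gave 0 to 2 genes called by edgeR (0 to 1 higher, 0 to 1 lower, 0 to 2 at 2-fold or more), the 2 being AMIGO3 and ENSG00000261915 without siAURKA replicate 2. The replicate block without both libraries numbered 2 called 2 genes, 1 higher and 1 lower, 2 at 2-fold or more (AMIGO3 and ENSG00000283515). These few genes were named after their values were seen. RLE factors, library totals, both filter settings, limma-voom with or without the replicate block, values divided by 4, the GC and length offsets and edgeR with the replicate block left 0 genes called.

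Camera called 2 lists, against 7 with the replicate block, 6 with the filter of 5 CPM, 6 with GC and length offsets, 4 with the replicate block without both libraries numbered 2, and 0 with an estimated correlation, with fry, or with the replicate block and an estimated correlation. Leaving out each library gave 0 to 4 lists, the 0 without siNC replicate 2 and the 4 without siNC replicate 1, siNC replicate 3 or siAURKA replicate 2. For the list mitosis (G2/M) the adjusted p was 0.62 with an estimated correlation, 0.86 by fry and 0.60 with the replicate block and an estimated correlation, and 1.912e-06 to 0.26 over the left-out libraries. For the list hypoxia and glycolysis these were 0.58, 0.86 and 0.60, and 0.00104 to 0.26, the highest again without siNC replicate 2. With an estimated correlation camera also uses fewer degrees of freedom; at those of the preset, a calculation chosen after the results were seen, the adjusted p would be 0.46 for mitosis and 0.20 for hypoxia and glycolysis, whose estimated correlations were 0.40 and 0.13. Other causes were not tested. Apart from the lists gained, and PLAT, CCND1 and ADM adjusted over their lists alone, the replicate block changed no other call of edgeR or camera.

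Among named genes none of which edgeR called, some changed sign. Over the left-out libraries the log2 fold change ran from -0.30 to 0.023 for CYP2E1 (the last without siNC replicate 1). It ran from -0.90 to 0.0014 for PLAUR, -0.65 to 0.0011 for ETV5, -3.15 to 0.36 for CSF2, -1.70 to 0.59 for CXCL8, -1.055 to 0.12 for TNFAIP3, -1.58 to 0.37 for ASNS, -1.03 to 0.075 for PSAT1, -1.26 to 0.31 for SQSTM1, -0.62 to 0.13 for SERPINA1, -0.92 to 0.36 for KRT19 and -0.48 to 0.15 for SOX9, all above 0 only without siNC replicate 2. TEK ran from -0.098 (without siAURKA replicate 1) to 1.61, and VWF from -0.15 (without siAURKA replicate 2) to 1.41. With the replicate block and without both libraries numbered 2, SPARCL1 was at -0.15, CXCL8 0.17, ASNS 0.11, PSAT1 0.036, KRT19 0.086 and VWF -0.33. Fits with 1 library left out had no replicate block and kept its same-numbered partner, so a sign change there can reflect the broken pair. Of the genes above 0 only without siNC replicate 2, PLAUR, CSF2, TNFAIP3 and SQSTM1 were lower in 3 of 3 pairs. The others were not. The cause was not tested. In simulated counts, which had a replicate effect built in, edgeR without the block recovered no 4-fold change. If the real libraries are paired in that way, its count of 0 says little at this spread.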

Other observations

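The tests of gene families, of overlapping loci, of multiples of 4, of the mitosis list against DNA replication, and of the other splits for the edgeR count, the mitosis list and DESeq2 with the replicate block were chosen after the results they bear on were seen. Kinetochore genes of the CENP family that were not in the mitosis list were higher after siAURKA, with a median log2 fold change of 0.21 over 20 genes, 10 higher in all 3 pairs and 0 lower. Camera gave an adjusted p of 0.032 over the 10 families tried, 0.0098 with the replicate block and 0.98 with an estimated correlation. The 29 kinesins outside the mitosis list had a median of 0.10 (adjusted p = 0.58) and the 22 tubulins -0.07 (0.58).

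C2H2 zinc finger ZNF genes had a median of 0.15 over 435 genes and an adjusted p of 0.0105 (0.98 with an estimated correlation), with pair medians of -0.01, 0.35 and 0.19. Replication-dependent histones were at 0.47, -0.23 and 0.37 in the pairs (adjusted p = 0.16). Ribosomal proteins (79 genes, median -0.06), proteasome subunits (37, 0.01), nuclear genes of the respiratory chain and ATP synthase (87, -0.01), chaperones (24, -0.01) and translation initiation factors (54, -0.01) had adjusted p-values from 0.72 to 0.91.

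The mitosis list was higher in each pair. No pair supplied more than 59.5% of the sum of the pair medians, the share of pair 2. With the replicate block, offsets for GC content and length left the median at 0.41 (bootstrap interval 0.31 to 0.51) against 0.45 without them. These values argue against a single pair or such trends as the whole cause of the list's median. The bootstrap intervals here cover spread between the list's genes, which are correlated, and not between libraries. The mitosis median exceeded that of DNA replication by 0.16, 0.63 and 0.34 in the pairs, but the bootstrap interval in pair 1 ran from -0.055 to 0.29, so more cells at every stage of the cycle stay open. A larger share of cells in G2 or mitosis after loss of Aurora A, which acts there, is also a candidate explanation; cell cycle phase was not measured. The pattern itself stays open, because the call is lost with an estimated correlation and without siNC replicate 2 (adjusted p = 0.26 by camera). The latter fit kept siAURKA replicate 2 without its same-numbered partner.

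Genes with large changes often overlapped others: 23 of 117 genes called at 2-fold or more by DESeq2 with the replicate block (19.7%) had over 50% of their exonic bases inside other genes' exons, against 7.48% of the 14741 annotated genes with an adjusted p (Fisher's exact test, p = 1.552e-05). Reads divided differently between overlapping genes may produce such changes, and a first comparison, the median change of summed loci over that of the genes alone, gave 0.0483. It was set aside after it was seen because abundant partners dominate those sums, and was replaced by 8 loci where the gene's own change should shift the sum by at least 0.3 on the log2 scale. There the sum showed a median of 70.2% of that shift (bootstrap interval -0.1005% to 120.6%), with -4.28% for ZBED6 and 114% for SPECC1L; 3 loci kept under 50% and 5 more, so division of reads and a true change cannot be told apart for these loci as a set.

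Low values favoured multiples of 4. They made up 31.2% of values from 1 to 24. Equal frequencies would give 25%, and counting each fragment exactly 4 times would give 100%. Coverage converted with too short a read length and rounded up per transcript may give values just above multiples of 4; in genes with 2 or more transcripts these were 1.95 times as frequent as the next values. The ratio was also 1.446 in genes with 1 transcript, where rounding once would not add it, so the values leave this open. Frequencies also fell with rising value (740 genes at 3, 376 at 6 and 327 at 7 in siNC replicate 1), which by itself raises this ratio. No biological explanation of these multiples was tested.

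With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. edgeR called 0 genes in the real split, which all 10 of the 10 splits reach by construction, so that count tests nothing; the highest other called 6. In 9 of the 10 camera called at least the 2 lists of the real split, the highest other calling 8, and in 6 of the 9 others the mitosis list had an adjusted p below 0.05 (lowest 0.00019, against 3.139e-05 in the real split). With the replicate block the 10 splits make 7 distinct fits, since splits that separate 1 pair come in equivalent twos. DESeq2 called at least the 246 genes of the real split in 3 of the 10 splits, or 2 of the 7 fits. The other of these fits compares siNC replicate 2 with siAURKA replicate 2 alone. Those libraries also differ by treatment, so its count of 1173 genes alone cannot tell a structure of the samples from the treatment. The matching fits for the libraries numbered 1 and 3 called 27 and 120 genes. All of these fits carry the treatment, so the larger count is particular to the libraries numbered 2. Among the 4 splits that separate all 3 pairs, as the real one does, the others called 22, 33 and 14 genes, and had 243, 364 and 361 unadjusted p-values below 0.05 by edgeR with the replicate block against 1591.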
